A study of Rattus norvegicus with 4 samples.

How the data were processed

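RNA was measured on 4 arrays of 1 slide, 1 for each combination of tissue (cerebellum or prefrontal cortex) and state (control or depressive). Per the labels' protocols, 50 rats were killed 1 week after the swimming test, blood was washed out with saline through the heart, and slices 1 mm thick were cut 3.2 to 4.2 mm in front of the bregma (prefrontal cortex) and 9.8 to 10.8 mm behind it (cerebellum). Equal amounts of RNA of 4 rats were pooled and 400 ng labelled with Cy3, per the labels' protocols.

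Per the file headers, the array scans were processed with Agilent Feature Extraction 10.7.1.1 under the protocol GE1_107_Sep09. The deposited scanner files give a processed intensity per spot, from which background was subtracted within the array, and flags per spot, per the file headers. The header names genome build rn4, and no coordinates are printed here. The deposited value table lists 23207 probes as a linear intensity, with medians of 0.327, 0.324, 0.332 and 0.332 for the control cerebellum, depressive cerebellum, control prefrontal cortex and depressive prefrontal cortex samples. Set against the scanner files, each column is the mean intensity of a probe divided by 1 number per array, and how that number was chosen and the probes selected is not given in the sources used here.

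Samples were grouped by title, source name and characteristics. On the depressive samples the description field names the other tissue. Each value-table column was correlated with each scanner file on the log2 scale. The column of each sample matched a single scanner file at r of 0.99994 or more, but the columns of the control prefrontal cortex and depressive cerebellum samples matched the files linked to each other, and correlated at 0.933 with their own linked file. The table, which is keyed by sample, was followed, a choice made after the files were seen, and results for files as linked are printed beside the main counts. The names of the linked files give the same reading. Tissue markers give the same tissues, but they cannot tell a control from a depressive array.

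Flagged outlier spots and control spots were left out, log2 of the processed intensity was averaged over the spots of a probe, and each array's 75th percentile was subtracted. The 75th percentile was 4020 for control cerebellum, 4369.5 for depressive cerebellum, 3116 for control prefrontal cortex and 3278 for depressive prefrontal cortex. Probes have 1, 2 or 10 spots. A probe counted as well above background if 50% or more of its spots carried that flag, a gene if any of its probes did. Of 30367 probes, 22031 carry a RefSeq accession and 18355 were named through a table of assembly GRCr8, without versions, giving 15443 genes. The other 12012 probes stayed unnamed. A gene with several probes (2668 genes) was represented by the brightest. Where a single array of a pair was not well above background, the fold is a bound against the higher of the lowest signal of a probe well above background and the probe's own signal. Genes not well above background on both arrays of a pair were left out of its count. Saturated genes numbered 0.

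Additive error, an estimate of background noise in the file headers, was 6.99 on the depressive cerebellum array and 4.03, 4.20 and 4.02 on the others. The lowest signal of a probe well above background was 8.36 and 7.35 on the control and depressive cerebellum arrays and 8.98 and 5.64 on those of the prefrontal cortex. The SE printed is that between spots at the same brightness, except for the limma fit, where it is the SE of the fit. On the 4 arrays, in the order control and depressive cerebellum, control and depressive prefrontal cortex, 1.78%, 1.51%, 0.989% and 1.26% of probes with 2 spots differed by 2-fold or more between spots.

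With 1 array per group no test was made within a tissue. A limma fit (lmFit and eBayes) of state with tissue as a block, over 11624 genes well above background on all 4 arrays and with Benjamini-Hochberg adjustment, was added after the data were seen. Genes at 2-fold or more were counted, the correlation was taken across genes, and the median log2 fold of 36 gene lists fixed before the data were examined was placed among 10000 random lists matched in 20 expression bins. Of 521 list genes 492 were on the array. Of 72 list and tissue pairs 19 fell outside the central 99%, and this range was chosen afterwards. Random genes were drawn singly, which makes no allowance for list members that move together. The percentile measures no spread between pools. Genes named per tissue are the 8 largest rises and falls among genes with a usual symbol whose brighter array reaches the 25th percentile of probes well above background and whose probes share a sign, Gh1 and Prl, and up to 4 members with the largest change of each list described, with the 5 brightest markers per tissue and up to 8 genes at 2-fold in both tissues. Acsm5, Lrat, Slc15a1, Oasl, Bpgm, S100a8, S100a9, Nr4a3 and, in the prefrontal cortex, Grm5 were named after their values were seen. Some genes that these rules name are not reported here.

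The steps were tested on simulated data with known changes in 15443 genes. In the simulated cerebellum comparison 100% of genes changed 2.5-fold or 4-fold passed 2-fold, 0% of those changed 1.5-fold did, and 35 of 12414 unchanged genes passed. In the simulated prefrontal cortex comparison the same shares were found and 20 of 12148 unchanged genes passed. Changed genes were drawn only from genes well above background and brighter than the median probe of the control array. Spot noise was set from the median spread between spots on that array. Both simulated arrays had the same background flags, so no fold was a bound. The shares therefore do not cover dim genes and bounds, which make up most genes at 2-fold in the data. For the fit with tissue as a block, on 11624 genes with normal noise, 100% of genes changed 4-fold, 100% of those 2.5-fold lower, 91.2% of those 2.5-fold higher, 21.2% of those 1.5-fold lower, 17.6% of those 1.5-fold higher and 2 of 11424 unchanged genes were called. All genes of an expression bin were given the same SD there, unlike real genes. These shares therefore do not hold for the data, where Hbb-b1, at a log2 fold of 2.70 in the fit, was not called.

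Alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, scaling to the median or to the 75th percentile of detected probes, other filters on dim genes, the mean over a gene's probes, thresholds of 1.5-fold and 3-fold, the value table and other pairings. Normexp was run on the median spot and background signals, where the mean spot signal had been planned. Added after the data were seen were the files as linked, the filters on spots, brightness and neighbouring spots, the correlation without haemoglobin genes, and further scalings of the lists and named genes. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.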

Results

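Gene expression was measured in the cerebellum and the prefrontal cortex of male rats with a 1-colour Agilent array, on which Cy3-labelled RNA of 1 sample is hybridised to gene probes. The rats came from 106 animals scored in the forced swimming test, in which the time a rat spends immobile in water is taken as a depressive-like behaviour. Rats with depressive-like behaviour and rats with average scores, called control here, each gave 1 RNA pool of 4 animals per tissue, so that there were 4 groups with 1 array each. No difference within a tissue therefore has a replicate check, and it describes these pools only. Across tissues, a fit of the depressive state with tissue as a block leaves 1 residual degree of freedom and is given with the last comparison. Of 30367 probes, 23759 were well above background on the control cerebellum array, 22206 on the depressive cerebellum array, 23124 on the control prefrontal cortex array and 23371 on the depressive prefrontal cortex array. The number of arrays limits the precision. Spread between repeated spots of a probe, which is technical, is given as SE where a value is printed with an error, except for the fit across tissues.

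The first comparison asked whether the arrays carry the tissue that their labels name. All 18 measured cerebellum markers were at least 2-fold higher on the cerebellum array, with a median log2 difference of 5.52 in control and 5.51 in depressive rats. Pcp2, a Purkinje cell gene, gave a signal of 156486 on the control cerebellum array and 619 on the control prefrontal cortex array, a 196-fold difference. Neurod1 was 56.7-fold, Car8 51.6-fold and Grm4 14.7-fold higher in control cerebellum than in control prefrontal cortex. Of 18 cerebral cortex markers, 15 were at least 2-fold lower in cerebellum in both states, with medians of -6.66 and -6.62 on the log2 scale. Crym was 18.4-fold and Npy 7.44-fold lower in control cerebellum, whereas Cux2 was 1.91-fold and Neurod6 1.84-fold lower, and Neurod2 was 1.39-fold higher there. These arrays are those whose values match the deposited value table of each sample at a correlation of 0.99994 or more. The scanner files linked to the control prefrontal cortex sample and to the depressive cerebellum sample match each other's value-table column, and this reading was taken as the leading one after the files had been compared.

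Between tissues, 3092 of 12859 genes measured in control rats differed by 2-fold or more, 1268 higher and 1824 lower in cerebellum. In depressive rats 3078 of 12649 genes did, 1175 higher and 1903 lower in cerebellum. With scanner files taken as linked to their samples, these tissue comparisons gave 219 and 103 genes.

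In the cerebellum, the question was which transcripts differ between depressive and control rats. Growth hormone and prolactin, hormones of the anterior pituitary, were lower on the depressive array. Gh1 had a signal of 882 on the control array and 7.12, not well above background, on the depressive array, which is at least 130.4-fold lower. Prl had 259.6 and 7.68, at least 36.7-fold lower. After normexp background correction their log2 folds were -3.84 and -2.14, against -7.03 and -5.20. Haemoglobin transcripts were higher: Hbb, a beta chain of haemoglobin, went from 1530.06 to 12504.5, a 7.52-fold difference (log2 fold 2.91, SE 0.06 between spots), and Hbb-b1 was 7.43-fold, Hbb-bs 7.08-fold, Hbe2 7.38-fold and Hba-a1, an alpha chain gene, 3.34-fold higher. Hbb, Hbb-b1, Hbb-bs and Hbe2 are similar beta-type genes, so it is uncertain which of them gave the signal.

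Of 12582 named genes measured in the cerebellum, 219 (1.74%) differed by 2-fold or more, 96 higher and 123 lower in depressive rats, and the median over all genes was -0.03 on the log2 scale. In 52 of the genes that were higher and 114 of those that were lower the dimmer array was not well above background, so that the fold is a lower bound. The other genes named as lowest were Tacr3, a tachykinin receptor, at 2.45-fold lower (signal 1621.97 against 720.3, log2 fold -1.29, SE 0.10), and Cck, the neuropeptide cholecystokinin, at 1.88-fold lower (2156 against 1248). Gpx2 was 2.13-fold lower, but its spots gave log2 folds of -1.95 and -0.24, and against -1.09 the mean over its probes gave -0.61 and normexp -0.70. Acta1, skeletal muscle actin, was 2.05-fold lower, with spots at -1.83 and -0.25. Rpl39l1 was 2.001-fold and Myog 1.75-fold lower, each from a single spot. Normexp took Acta1 to -0.77 and Rpl39l1 to -0.56 on the log2 scale, and both also lay under 2-fold after quantile normalization, at -0.97 and -0.94. The genes with the largest rank by fold among those higher were Btbd35f9 (at least 59.2-fold), Or9i13 (at least 41.8-fold), Tmem95 (36.4-fold), C3h20orf144 (at least 33.6-fold), Vom2r28 (at least 20.8-fold) and Dapk2 (7.63-fold), each measured on a probe with a single spot. Vom2r28 has 2 probes, and their mean gave a log2 fold of 2.21 against 4.38. After normexp the log2 folds of these 6 genes, in the same order, were 2.94, 1.84, 3.34, 1.70, 1.97 and 1.92, against 5.89, 5.38, 5.19, 5.07, 4.38 and 2.93. Each of these 6 spots lay within 2 rows and 2 columns of 4 to 8 other spots that were also at least 2-fold higher, while the spots of Hbb and Hbb-b1 had 0 such neighbours. Without genes that have a spot beside another that moved the same way, 78 genes remained, 16 higher and 62 lower. The balance of higher and lower genes turned with the processing: normexp background correction gave 25 higher and 6 lower, genes well above background on all 4 arrays 36 and 7, quantile normalization 118 and 77, and the deposited values 93 and 75. The count was 3092 with scanner files taken as linked to their samples.

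**Figure D1:**
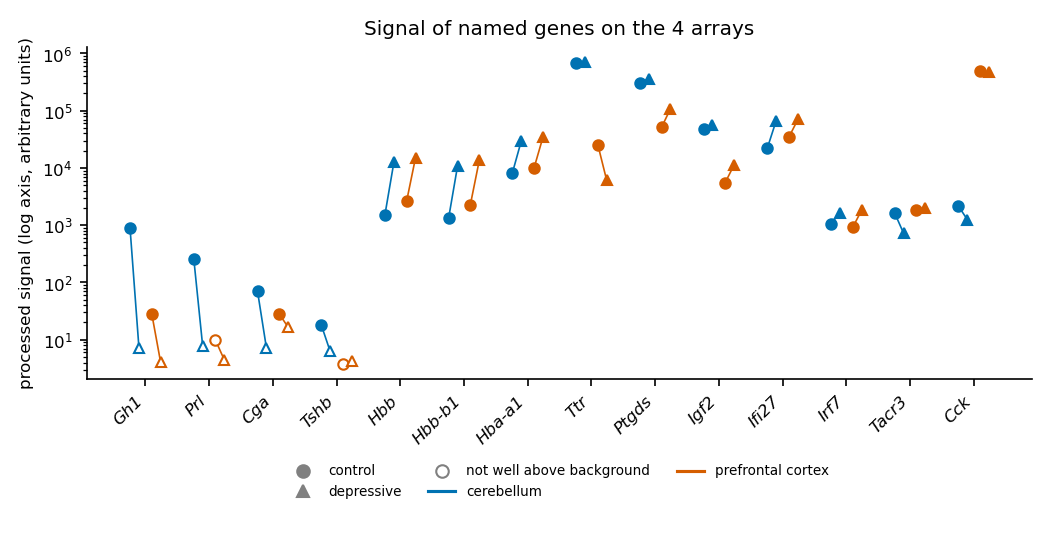
Processed signal (log axis, arbitrary units) of 14 genes on the control (circles) and depressive (triangles) arrays of the cerebellum (blue) and prefrontal cortex (orange), with open symbols where the probe was not well above background and a line joining the arrays of a tissue. Gh1 stood at 882 on the control cerebellum array and 7.12 on the depressive one, and Hbb was higher on the depressive array of both tissues.

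Gene lists fixed before the data were examined gave the following picture of the cerebellum. Of 9 measured genes of the pituitary list, 6 were below 0 and 4 at least 2-fold lower (median -0.83, but -0.28 after normexp, -0.24 with the mean over probes and -0.09 in the value table), and besides Gh1 and Prl these were Cga, the common subunit of glycoprotein hormones, at least 10.4-fold lower, and Tshb, a subunit of thyrotropin, at least 2.70-fold lower. Pomc, Lhb and Fshb, further hormone genes, had log2 folds of -0.11, 0.06 and 0.03. Of 11 choroid plexus genes, which mark the epithelium that secretes cerebrospinal fluid, 10 were higher, with a median of 0.59 on the log2 scale. Kcnj13 was 1.76-fold, Sostdc1 1.72-fold, Kl 1.69-fold and Aqp1 1.62-fold higher, and Ttr, transthyretin, had a log2 fold of -0.07. Of 19 major histocompatibility and interferon response genes 17 were higher (median 0.20), with Ifi27 at 2.79-fold, Irf7 at 1.40-fold, Ifit3 at 1.35-fold and Isg15 at 1.28-fold. Of 9 blood cell genes 8 were higher (median 0.53), among them Alas2, the first enzyme of haem synthesis in red cell precursors, at 2.83-fold. Of 13 microglia genes 10 were higher with a median of 0.10 (0.06 with the mean over probes), including P2ry12 at 1.17-fold, and of 12 meningeal and fibroblast genes 9 were higher with a median of 0.12.

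Of 21 glutamate receptor genes 18 were below 0 on the depressive cerebellum array, with a median of -0.11, and -0.07 after quantile normalization. Grm5 was 2.14-fold lower at a signal of 68.1 against 34.6 (SE 0.46), Grik3 1.76-fold and Grin1 1.22-fold lower. In the prefrontal cortex Grm5 was 1.71-fold lower at 827 against 507 (SE 0.08), while 9 of 22 glutamate receptor genes were above 0 there. Of 18 synaptic vesicle genes in the cerebellum 16 were below 0 with a median of -0.08, including Syt1 at 1.21-fold and Syn1 at 1.16-fold lower. Slc17a6, a vesicular glutamate transporter, was 1.31-fold higher. The cerebellum markers themselves had a median of -0.11, with 17 of 18 below 0 and Zic2 at 1.35-fold lower, and -0.05 in the value table. Among 14 genes of thyroid hormone and retinoid handling 8 were above 0 with a median of 0.07 (0.02 in the value table), with Slco1c1 at 1.22-fold higher and Rara at 1.27-fold lower. Each list median in this paragraph and the one before lay outside the central 99% of 10000 random lists of the same size matched on expression, a range chosen after the medians had been seen. Random genes were drawn singly, so the range makes no allowance for list members that move together. It also measures no spread between pools. Within that range lay the lists of GABA synthesis and receptors (median -0.07), dopamine and noradrenaline signalling (-0.10) and serotonin signalling (-0.09). Neuropeptides (-0.05) and opioid and cannabinoid receptors (-0.08) lay there too. So did housekeeping genes, all 11 below 0 (median -0.03), and oxidative phosphorylation genes, 16 of 20 below 0 (median -0.03). A count below 0 alone therefore does not set a list apart.

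In the prefrontal cortex the same haemoglobin genes were higher on the depressive array. Hbe2 was 5.95-fold, Hbb-b1 5.66-fold, Hbb 5.47-fold (log2 fold 2.45, SE 0.06), Hbb-bs 4.92-fold and Hba-a1 3.29-fold higher (log2 fold 1.72, and 2.07 with the mean over probes). Hp, haptoglobin, the plasma protein that binds free haemoglobin, was 2.34-fold higher (signal 124.7 against 306), but under 2-fold after normexp, at a log2 fold of 0.78 against 1.22. Ttr was 4.44-fold lower, with a signal of 25617 on the control and 6076 on the depressive array (log2 fold -2.15, SE 0.05). Pcp2 was 2.35-fold and Cbln1, a granule cell gene of the cerebellum, 1.72-fold lower. Gh1 was at least 5.35-fold lower, from a control signal of 28.7, but after normexp its log2 fold was -0.58 against -2.42, which is under 2-fold. Prl was not well above background on either prefrontal cortex array.

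Of 12544 named genes measured in the prefrontal cortex, 103 (0.821%) differed by 2-fold or more, 58 higher and 45 lower in depressive rats, of which 31 and 32 are bounds. Further genes named by rank were Samd13, 4.74-fold higher from a single spot, and Ndc80, a kinetochore gene, 3.93-fold higher with spots at log2 folds of 0.63 and 3.32. After normexp their log2 folds were 1.103 and 1.19, against 2.25 and 1.97. Prr19 was 3.52-fold lower with spots at -4.26 and 0.63. Prdm11 was 1.85-fold lower (log2 fold -0.89, and -0.51 with the mean over probes), Ppp1r14bl 1.81-fold and Prss12, the brain protease neurotrypsin, 1.78-fold lower. The count was 14 (10 higher and 4 lower) after normexp background correction and 33 (24 and 9) among genes well above background on all 4 arrays, and 3078 with scanner files taken as linked to their samples.

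Among the lists, all 12 meningeal and fibroblast genes were higher on the depressive prefrontal cortex array, with a median of 0.75 on the log2 scale. Ptgds, prostaglandin D synthase, had a signal of 51142 on the control and 107598 on the depressive array, and Igf2 was 1.94-fold, Ogn 1.83-fold and Aldh1a2 1.82-fold higher. All 12 oligodendrocyte and myelin genes were higher, with a median of 0.30, and Mog was 1.32-fold, Ermn 1.32-fold and Mobp 1.29-fold higher. In the cerebellum the myelin list had a median of -0.04, with 5 of 12 genes above 0. Of 19 major histocompatibility and interferon response genes 16 were higher (median 0.21), with Ifi27 at 1.93-fold, Irf7 at 1.91-fold, Isg15 at 1.73-fold and Oas1a at 1.63-fold. Of 10 pericyte and smooth muscle genes 8 were higher (median 0.12), Myh11 at 1.21-fold and Vtn at 1.14-fold. Of 9 blood cell genes 7 were higher (median 0.20, and 0.13 after normexp), with Alas2 at 2.06-fold.

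The choroid plexus list had a median of opposite sign to that in the cerebellum, though not all of its genes did. Of 8 measured in the prefrontal cortex 5 were below 0, 4 of them at least 2-fold lower, with a median of -0.61, and -0.23 after normexp. Besides Ttr these were Sostdc1 at 2.59-fold, Otx2 at least 2.39-fold and Folr1 at 2.003-fold lower, all with control signals of 67.3 or less. Aqp1 (1.94-fold), Kcnj13 (1.49-fold) and Enpp2 (1.09-fold) were higher, as they were in the cerebellum. Sostdc1, Otx2 and Folr1 are also among 17 genes with a signal above the 75th percentile on both cerebellum arrays and at least 50-fold higher there than in prefrontal cortex, all of which were higher on the control than on the depressive prefrontal cortex array. Cerebellum markers had a median of -0.15, with 12 of 16 below 0, and besides Pcp2 the genes at 2-fold were Ppp1r17, at least 3.06-fold lower, and Gabra6, a receptor subunit of granule cells, 2.46-fold lower. Of 18 neuropeptide genes 13 were below 0 with a median of -0.10, and Penk and Sst were each 1.14-fold lower, while Nxph4 was 1.33-fold higher near background. Of 16 glucocorticoid response genes 11 were above 0 with a median of 0.05 (0.02 with median scaling and 0.07 after quantile normalization), Sult1a1 at 1.14-fold and Gjb6 at 1.12-fold higher and Cdkn1a at 1.09-fold lower. The prefrontal cortex medians in this paragraph and the one before, too, lay outside the central 99% of random lists. That of the glucocorticoid response genes did so narrowly, at percentile 99.53. Within that range lay cytosolic ribosomal protein genes, 18 of 19 below 0 (median -0.09), and oxidative phosphorylation genes, 18 of 20 below 0 (median -0.08).

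**Figure D2:**
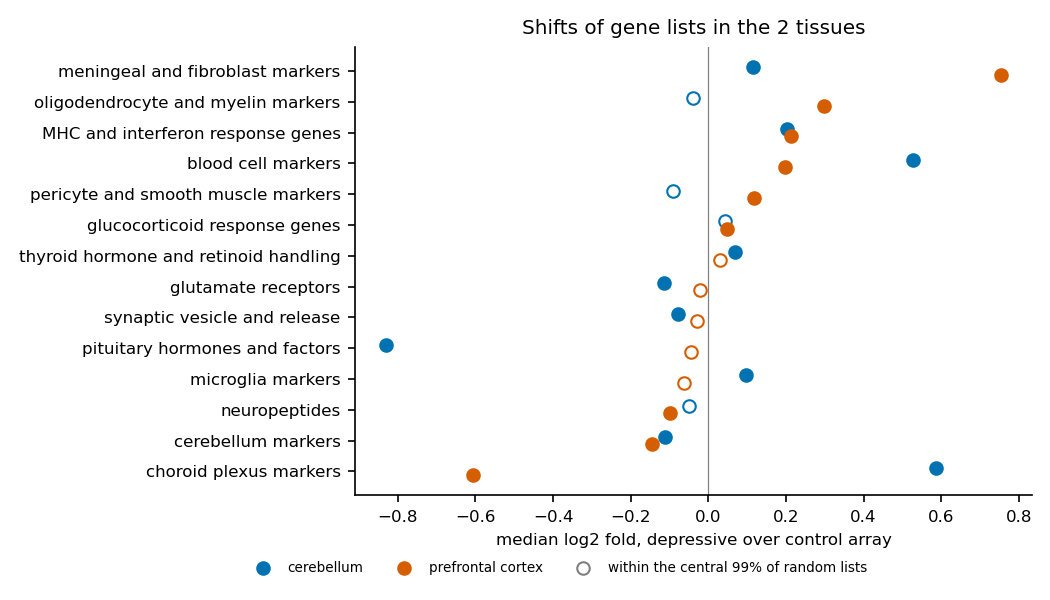
Median log2 fold of the depressive over the control array for 14 gene lists in the cerebellum (blue) and prefrontal cortex (orange), filled where the median lay outside the central 99% of 10000 random lists and open where it lay within. The meningeal list stood at 0.75 in the prefrontal cortex and 0.12 in the cerebellum, and the choroid plexus list at -0.61 and 0.59.

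The last comparison asked whether the depressive state moved genes the same way in both tissues. Over 11624 genes well above background on all 4 arrays, the folds correlated across genes at a Pearson r of 0.20 and a Spearman rho of 0.18. Genes are not independent replicates, and without 6 haemoglobin genes r was 0.13. The folds share no array. In a limma fit of the depressive state over these genes, with tissue as a block and 1 residual degree of freedom, 0 genes reached an adjusted p under 0.05 and 905 an unadjusted p under 0.05. The smallest adjusted p was 0.208, for Hba-a1, at a log2 fold of 1.73 (SE of the fit 0.05, not that between spots) and higher in both tissues. After normexp 5 genes reached it, Hbe2, Hba-a1, Hbb-b1, Hbb and Hbb-bs, with adjusted p of 0.00128 to 0.00297, and with scanner files as linked 8459 did. The fit takes the tissues as replicates, which the labels do not say come from separate rats. Without normexp Hbb-b1, at a log2 fold of 2.70 in the fit, was not called, so 0 genes does not show that no gene changed. Of 12124 genes measured in both tissues, 16 differed by 2-fold or more in both, of which 10 were higher in both, 2 lower in both and 4 opposite. Independent lists would share 0.18 higher, 0.10 lower and 0.28 opposite, so genes of opposite sign were above that number too, 3 of the 4 as bounds in both tissues. The higher genes included Hbe2, Hbb-b1, Hbb, Hbb-bs and Hba-a1, and Gh1 was lower in both, though not by 2-fold in the prefrontal cortex after normexp. Of the genes with opposite signs, Supt20hl1 was at least 3.72-fold lower in the cerebellum and at least 3.34-fold higher in the prefrontal cortex, and Slc35g1 at least 3.56-fold higher and at least 2.87-fold lower.

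**Figure D3:**
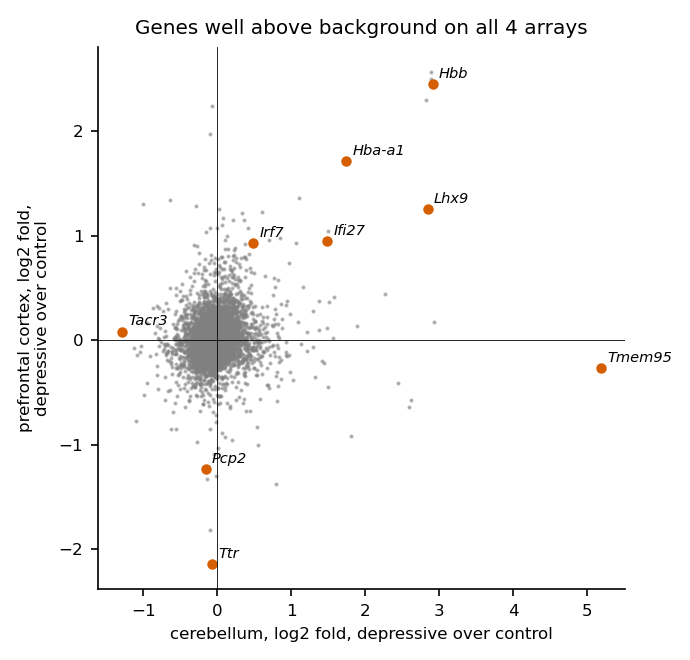
Log2 fold of the depressive over the control array in the prefrontal cortex against that in the cerebellum, with 1 point per gene for 11624 genes well above background on all 4 arrays and 9 genes named. Hbb lay at 2.91 and 2.45, Ttr at -0.07 and -2.15, and the correlation across genes was 0.20.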

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

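Of the results below, none of the differences between tissues was tested, since each group is 1 array and a difference between tissues in the effect of the depressive state has no spread to be set against. The choroid plexus list stood apart because its median log2 fold between depressive and control arrays had opposite signs in the tissues, 0.59 in the cerebellum and -0.61 in the prefrontal cortex, where normexp background correction gave -0.23 and, in the cerebellum, 0.56. The difference was not tested. The genes do not all take part alike: Ttr was at -0.07 in the cerebellum and at -2.15 in the prefrontal cortex, Sostdc1 was at 0.79 and -1.37, while Kcnj13 (0.81 and 0.57) and Aqp1 (0.70 and 0.96) were higher in both tissues. Sostdc1, Otx2 and Folr1, 3 of the 4 choroid plexus genes at least 2-fold lower in the prefrontal cortex, lay on its control array above its depressive array by 0.416%, 0.334% and 0.629% of their cerebellum level. Pcp2 and Cbln1, genes of cerebellar neurons, did so by 0.310% and 0.254%, and the median of 17 cerebellum-specific genes, which include these, was 0.221%. Ttr, which had the largest fall, is not among these 17 genes, so the shares say nothing about it. Of the 8 choroid plexus genes measured in the prefrontal cortex 5 were below 0, including Sostdc1, Otx2 and Folr1, and 3 were above 0. The sign of the list median in that tissue therefore rests on Sostdc1, Otx2 and Folr1. Its cause was not tested.

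Rpl39l1, a gene related to a ribosomal protein, was also of opposite sign, with a log2 fold of -1.001 in the cerebellum and 1.31 in the prefrontal cortex. Normexp gave -0.56 in the cerebellum. Its probe has a single spot, and the difference was not tested.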

How the results depend on the processing

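Settings chosen after seeing the data were the files as linked, the filters on spots, neighbours and brightness, the correlation without haemoglobin genes, median scaling and scaling to detected probes for gene lists, every setting for single genes other than Gh1 and Prl, median scaling for Gh1 and Prl, and the fit with tissue as a block. Median scaling, scaling to detected probes, quantile normalization, the value table and the mean over probes gave counts of genes at 2-fold within 1.5 times, in both tissues. Of the 219 cerebellum genes 216, 215, 168, 77 and 204 were shared with these, and of the 103 prefrontal cortex genes 102, 100, 101, 79 and 93. In the cerebellum, quantile normalization gave 118 higher and 77 lower (60.5% higher) and the deposited values gave 93 and 75 (55.4%), against 96 and 123 (43.8%). The cerebellum count was 31 (25 higher, 6 lower) after normexp, 43 (36 and 7) for genes well above background on all 4 arrays, 347 without a filter or bounds, 580 at 1.5-fold, 81 at 3-fold, 44 where every spot passed, 29 (23 and 6) for bright genes and 78 without spots beside another that moved the same way. The prefrontal cortex count was 14 (10 higher, 4 lower), 33 (24 and 9), 259, 348, 30, 28 and 18 under the first 7 of these. Bounds and dim genes are removed by the construction of the filters and damped by the offset of normexp; the causes were otherwise not tested. Signal over background limits these counts, since most genes at 2-fold are dim.

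Pairing by the description field gave 3029 genes in the cerebellum and 3180 in the prefrontal cortex, a correlation of -0.97, and tissue marker medians of -5.51 (cerebellum) and 6.62 (cortex) in depressive rats. Files as linked gave 3092 and 3078 genes, 219 and 103 genes between tissues, and tissue marker medians of 0.11 and 0.15 for cerebellum and 0.0773 and 0.0355 for cortex markers. By tissue markers, both readings set arrays of different tissues against each other within a labelled tissue. Pairing by the names of the linked files gave the main values. After normexp the correlation was 0.28, without haemoglobin genes 0.13, and the cortex marker medians were -4.58 in control and -4.87 in depressive rats; the cause was not tested.

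Of 19 gene list medians, none of which was run with files as linked, the sign turned under 1 setting alone, the pairing by the description field, for 8: in the prefrontal cortex cerebellum markers 5.46, glucocorticoid response -0.10, pericyte -0.38 and choroid plexus 5.49, and in the cerebellum glutamate receptors 1.18, meningeal -0.88, choroid plexus -5.38 and synaptic vesicle 0.43. The 33 values of named genes were run under normexp, quantile normalization, median scaling and the mean over probes, and the other pairings were run for Gh1 and Prl alone. No sign turned in these runs, and 22 moved under normexp beyond their SE between spots. The pituitary list in the cerebellum was at -0.28 after normexp, with Gh1 at -3.84 (-0.58 in the prefrontal cortex) and Prl at -2.14, at -0.24 with the mean over probes and at -0.09 in the value table. In the value table the cerebellum markers in the cerebellum were at -0.05 and thyroid hormone and retinoid genes at 0.02, and the choroid plexus list in the prefrontal cortex at -0.23 after normexp. With the mean over probes, Vom2r28 was at 2.21, Gpx2 at -0.61, Hba-a1 in the prefrontal cortex at 2.07 and Prdm11 at -0.51. A slide block was not run, since all arrays lie on 1 slide. Within a tissue no paired analysis was possible because each group has 1 array. With tissue as a block, limma gave 0 genes at an adjusted p under 0.05, 0 after quantile normalization and 5 after normexp, for which the cause was not tested. Files as linked gave 8459, since that reading sets the tissues against each other.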

Other observations

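All tests of explanations in this part were chosen after the results they bear on had been seen, as were the lists of erythroid, leukocyte and platelet, and other pituitary genes used in them. The tests of pituitary RNA, whole blood and RNA change were recast after the outcomes of earlier versions had been seen. Of genes whose every spot, with at least 2 spots, passed 2-fold, 15 were higher and 29 lower in the depressive cerebellum, and 21 were higher and 7 lower in the depressive prefrontal cortex. In the cerebellum 28 of the 29 lower ones are bounds, with Tacr3 the exception, against 2 of the 15 higher ones, and the balance was the other way among bright genes, 23 higher and 6 lower. In each tissue 5 of the higher ones are haemoglobin genes. Others in the cerebellum were Slc15a1 at 3.71-fold, Lrat, which esterifies retinol, at 2.92-fold and Acsm5 at 2.59-fold higher. Oasl, an interferon-induced gene, was at least 2.25-fold higher in the cerebellum and at least 2.26-fold higher in the prefrontal cortex by every spot.

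Immediate early genes, which respond to neuronal activity, had medians of 0.04 in the cerebellum and 0.06 in the prefrontal cortex. There, 11 of 19 and 16 of 20 genes were above 0. Both medians lay within the central 99% of random lists, a range chosen after the medians had been seen. In the prefrontal cortex the median was only just within it, at percentile 99.48. The glucocorticoid response list of that tissue, counted as outside, was at percentile 99.53 with a smaller median of 0.05. The range therefore does not set these lists apart. Nr4a3 was 1.54-fold higher in the cerebellum. Genes of the stress axis and glucocorticoid receptors had medians of -0.00393 and 0.00318 and 0 members at 2-fold in either tissue. Serotonin signalling genes had medians of -0.09 and -0.06, and dopamine and noradrenaline genes -0.10 and -0.05, also with 0 members at 2-fold.

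Pituitary hormone transcripts were higher on the control than on the depressive cerebellum array, Gh1 and Prl by the largest folds among the genes named as lower. RNA of pituitary cells in the control pool may be the source, but this stays open: of 7 hormone genes 4 (57.1%) were at least 2-fold lower, while Pomc, Lhb and Fshb, at control signals of 1116, 423 and 41.9, had log2 folds of -0.11, 0.06 and 0.03, and an earlier version on the 4 genes alone, which gave 100%, could not have decided it. A blemish on single spots is argued against, because the smallest log2 difference over the 4 spots of Gh1 and Prl was 5.10. A second list of pituitary genes had a median of 0.056 over 7 measured genes, too few and several too bright in cerebellum itself to show a small share, and a lower level of hormone transcripts in depressive rats also stays open, untested. For the trace of Gh1 on the control prefrontal cortex array, carry-over of cerebellum control RNA was considered. The excess of Gh1, 3.63% of the cerebellum level, was 16.5 times the median of 0.221% for 17 cerebellum-specific genes, all of which were above 0. This does not settle whether carry-over is the whole cause, since it rests on 1 gene near background. Its signals were 28.7 on the control array and 4.03, not well above background, on the depressive one. Its difference lay under 2-fold after normexp, and the 17 genes are brighter in cerebellum than Gh1.

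Haemoglobin transcripts were higher on both depressive arrays. More whole blood in the depressive pools cannot be told apart from other sources, although both medians below met the bound that the first version of the test set against it, which took no account of signal levels. The leukocyte and platelet list had a median of -0.14 in the prefrontal cortex, with 9 of 11 genes below 0 (S100a8 at -0.60 and S100a9 at -0.65, which a later version used alone, against Ppbp at 0.26 and Lyz2 at 0.13), and of -0.12 in the cerebellum, but 6 of 11 genes in the prefrontal cortex and 9 of 11 in the cerebellum lay close to background or at levels that would hide a small share, and the spread between pools is unknown. Red cell precursors stay open too: the higher of the erythroid list's medians was 0.17, in the cerebellum, where Alas2 was 2.83-fold higher while Bpgm was 1.02-fold higher from a high level, and the median was -0.00942 in the prefrontal cortex. A difference between depressive and control rats in red cells or their transcripts stays open, untested.

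Spots that were at least 2-fold higher on the depressive cerebellum array lay together. Of 318 such spots 69.2% had another within 2 rows and 2 columns, 6.35 times as often as spots placed at random (10.9%), which is consistent with a blemish on the array surface. The spots that were lower were 1.67 times as often neighbours, and in the prefrontal cortex the ratios were 2.35 for higher and 2.52 for lower spots. A change of RNA as the general source cannot be told apart from it: 10.3% of 175 probes with 2 spots and a higher spot had both higher, but noise on dim probes could also give a low share, and it was 14.6% in the prefrontal cortex.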
